A study of Mus musculus with 18 samples.

How the data were processed

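Poly(A) RNA was sequenced from Neuro-2A cells, primary mouse astrocytes and BV-2 cells that had received either a mix of 3 microRNA mimics or the control mimic cel-miR-67, at 25 nM for 24 h. Each cell type had 3 libraries per arm, which gave 18 libraries in 6 groups. The libraries were made with the NEBNext Ultra II Directional kit and poly(A) selection, per the labels' protocols. Trimmomatic 0.39, STAR 2.7.10b and the genome build mm10 are named in the submitters' processing notes, without a role or an order. The counting tool and the annotation release are not given in the sources used here.

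The deposited table held 53342 genes, of which 21950 were protein coding and 0 lay on the mitochondrial genome. Per the file headers, the authors deposited raw read counts without normalization, and these values are expected counts here. In each library 35.7% to 42.4% of the genes had a value that was not whole, as when a read is shared among its matches. The authors also deposited log2 TPM values, in which every TPM of 1 or less was set to 0 on the log2 scale. Within a library, these TPM were the counts divided by gene length and a constant. Total counts ranged from 18.5 to 27.9 M per library, which limits the precision for genes with low counts. The chi-square per degree of freedom between replicates of a group ranged from 1.61 to 21.0, so no library repeated another.

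The annotation at hand was GENCODE M21 for mm10, and 53237 of the identifiers (99.8%) were found in it, 96.3% of them with identical coordinates. The 3′ UTR of a gene was the longest annotated one of at least 20 nt, which gave 20895 genes with a median of 968 nt and covered 95.1% of the protein-coding genes in the table. Seed sites were read from bases 2 to 8 of each mature microRNA. An 8mer site was ACTACTGA for miR-199a-3p, CGAGCTTA for miR-99b-3p, AACCACTA for miR-140-5p and GGTTGTGA for cel-miR-67. A 7mer-m8 site lacks the final A of the 8mer and a 7mer-A1 site lacks its first base. A gene counted as carrying a site if its UTR held an 8mer or a 7mer-m8.

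Counts were rounded and tested within each cell type with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the mix was compared with the control mimic by the quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. For the comparisons within a cell type, the plan written before the data were examined named limma on log2 TPM for a table of TPM and edgeR for a table of counts. The counts were used. That plan also fixed the gene lists, the site classes, the comparisons and most alternatives. Differences of the mix effect between cell types were tested as interaction contrasts in an edgeR fit of all 18 libraries with 6 group means. TPM are given as mean ± SD of 3 libraries, and log2 fold changes with their SE.

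Of 37 gene lists, 7 held cell type markers, 2 held reported targets of miR-199a-3p and miR-140-5p, and 28 held pathway genes. Lists with at least 5 tested members were compared with the other tested genes by camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a cell type. Site sets were tested by camera among the tested genes with an annotated UTR. Sites among the called genes were counted with Fisher's exact test, two-sided, adjusted over its family. Overlaps of calls between cell types were set against n1 × n2 / N. Each cell type had its own control libraries.

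The genes named in the text came from a rule. In each cell type it took the 8 largest falls and the 8 largest rises past the threshold with a mean TPM of at least 5 in the higher group and no overlap between the groups, and up to 4 members of each target or pathway list with the smallest adjusted p. Across cell types it took the 10 largest falls and the 10 largest rises shared by all 3, and the 3 smallest interaction p-values per pair. The 2 most abundant members stood for each marker list. Gene models without a symbol, pseudogenes and mitochondrial genes were left out. From this set, the text prefers genes that kept their call under every alternative, a preference made after the values were seen. A few genes that the rule took are not reported here.

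The labels number the libraries of each arm from 1 to 3, and whether the numbers pair the libraries was checked by correlating deviations from the group means. In Neuro-2A the same-number correlations were 0.587, 0.395 and 0.262, all above 0.1, so these numbers were taken to pair the libraries. The highest correlations of these mix libraries with a control of another number were −0.383, 0.245 and 0.169. A number 1 that stands apart in both arms also makes numbers 2 and 3 correlate across arms, so their pairing is less certain. Values with the replicate number as a block are printed where they changed a call or moved a count by over 1.5 times. The sample descriptions also give libraries of both arms a common number, 3 to 5 in Neuro-2A, 4 to 6 in BV-2 and 1 to 3 in astrocytes, in the same order. They do not say what that number marks, so the pairing rests on shared numbers in the labels and on the correlations.

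The tests were checked on simulated counts with 66 or 67 genes changed at each of the known folds. In the simulations within a cell type, a further set of genes was lowered by a small amount. Calls on that set entered the total of calls but were not counted as false. The false shares therefore hold only for that mixture, which changed far fewer genes than were called in the real astrocytes. In Neuro-2A (16160 genes) 4.48%, 62.7% and 80.3% of the genes changed 1.25, 1.5 and 2 fold were recovered, and 6.54% of calls were false. For astrocytes (17770 genes) the shares were 56.7%, 68.7% and 93.9%, with 10.8% false. In BV-2 (14961 genes) they were 29.9%, 73.1% and 92.4%, with 7.01% false. The difference between astrocytes and Neuro-2A (20308 genes) recovered 5.97%, 35.8% and 53.0%, with 7.35% false.

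The alternatives were limma on log2(TPM + 1) and log2(TPM + 0.1), median-ratio scaling, no filter on low counts, filters on TPM, a fit of all 18 libraries, the replicate block, no abundance trend, DESeq2 1.42.0, each library left out in turn, other UTR and site definitions, adjustment for UTR length and GC content, and an estimated correlation. Leaving out number 1 of both Neuro-2A arms, the filter of TPM above 1 and camera on the differences were added after the data were seen. So was limma on log2(TPM + 1) as an alternative to the counts. Untransfected cells and single mimics were not analysed here. Figures and permutation tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.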

Results

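The series asks which genes of neurons and glia respond to 3 microRNAs, miR-140-5p, miR-199a-3p and miR-99b-3p. Their mimics, synthetic copies that enter the silencing machinery, were transfected together into Neuro-2A cells (a mouse neuroblastoma line), primary mouse astrocytes and BV-2 cells (an immortalised mouse microglial line). The control arm received cel-miR-67, a nematode microRNA used as a negative control. RNA was sequenced from 3 libraries per arm and cell type after 24 h. Falls and rises are levels in the mix arm against the control mimic arm, since the series holds no untransfected cells. Neuro-2A libraries held 22.4 to 23.6 M counts in the mix arm and 20.9 to 22.3 M in the control arm. Astrocyte libraries held 21.8 to 23.8 and 23.9 to 27.9 M. BV-2 libraries held 24.4 to 25.6 and 18.5 to 24.2 M, the lowest in control replicate 3. The labels do not state whether the replicates of a group were independent cultures, so the p-values measure only the spread between libraries, which may be technical.

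Each cell type expressed its own markers. Neuro-2A libraries carried the neuronal tubulin Tubb3 at 542 ± 121 TPM (SD over 6 libraries) and the growth cone gene Gap43 at 219 ± 35.1 TPM. Astrocytes carried the intermediate filament gene Gfap at 5294 ± 365 TPM and the water channel Aqp4 at 1264 ± 587 TPM. These means and SDs pool both arms, and the SD of Aqp4 includes its fall in the mix arm. BV-2 cells carried the lysosomal Cd68 at 1824 ± 106 TPM and the signalling adaptor Tyrobp at 992 ± 47.2 TPM. The neuron, astrocyte, and microglia and macrophage marker lists averaged 121, 880 and 363 TPM in Neuro-2A, astrocytes and BV-2. The astrocyte cultures also held smooth muscle actin Acta2 at 1500 ± 276 TPM, the ciliogenesis factor Foxj1 at 716 ± 44.3 TPM, the oligodendrocyte lineage factor Olig1 at 626 ± 17.2 TPM and the complement gene C1qa at 179 ± 23.4 TPM. Their fibroblast and pericyte, ependymal, oligodendrocyte lineage, and microglia and macrophage lists averaged 158, 136, 103 and 63.1 TPM, and their neuron list averaged 29.6 TPM, with Gap43 at 102 ± 4.13 TPM. Acta2 made up most of the fibroblast and pericyte average, where the next gene, the collagen Col1a1, stood at 33.1 ± 6.56 TPM. All 12 microglia and macrophage, all 11 oligodendrocyte lineage and all 8 ependymal markers lay above the floor in every astrocyte library. Outside their own markers, Neuro-2A lists averaged at most 5.53 TPM and BV-2 lists at most 14.5 TPM, in each case for the astrocyte markers. In BV-2 that average came from the glycolytic enzyme Aldoc (136 ± 18.5 TPM), the only 1 of 10 astrocyte markers above the floor in all libraries, while Gfap lay at the floor. The endothelial list averaged 1.72, 1.28 and 7.28 TPM in Neuro-2A, astrocytes and BV-2.

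The largest fall shared by all 3 cell types was that of Cd151, a tetraspanin that anchors integrins at the cell surface. Cd151 (ENSMUSG00000025510, mm10 chromosome 7, 141467392 to 141471473), whose 3′ UTR holds a miR-199a-3p 8mer, fell from 307 ± 5.78 to 51.9 ± 4.59 TPM in astrocytes (SD, n = 3 per group). It fell from 179 ± 27.5 to 35.4 ± 7.45 TPM in Neuro-2A and from 27.8 ± 0.728 to 9.94 ± 0.888 TPM in BV-2. The vesicle fusion gene Vamp3 (ENSMUSG00000028955, mm10 chromosome 4, 151047300 to 151057963), with 8mers of miR-199a-3p and miR-99b-3p, changed by −1.97 ± 0.0367, −1.18 ± 0.0635 and −1.23 ± 0.0593 on the log2 scale in astrocytes, Neuro-2A and BV-2 (SE). The osteopetrosis-linked lysosomal gene Ostm1, with a miR-140-5p 8mer, changed by −1.51, −1.03 and −1.12 in that order, and the filopodial motor Myo10 by −1.32, −1.24 and −1.08. The transcriptional repressors Zhx1 (−1.53, −1.05 and −0.93) and Nacc1 (−1.30, −1.18 and −0.93) and the chaperone regulator Bag2 (−0.89, −1.31 and −0.98) fell in each cell type and carried sites of the mix. The glycosyltransferase Mgat4b fell by 1.31, 1.08 and 0.84 without a site. The ferritin heavy chain Fth1 changed by −0.85, −1.70 and −1.04 without a site, and it is uncertain because its reads can be shared with pseudogenes.

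Genes that rose in all 3 cell types were led by Pop5, a subunit of the RNA-processing enzymes RNase P and MRP. Pop5 (ENSMUSG00000060152, mm10 chromosome 5, 115235836 to 115245351) rose from 4.18 ± 0.809 to 15.0 ± 1.67 TPM in astrocytes and from 19.3 ± 3.15 to 34.2 ± 1.41 TPM in BV-2 (SD, n = 3), and by 1.34 ± 0.108 on the log2 scale in Neuro-2A (SE). The kinase Uhmk1 (0.96, 1.36 and 1.07), the SUMO-activating enzyme Sae1 (1.36, 1.04 and 0.80) and the mitochondrial phosphatase Pgam5 (1.36, 1.08 and 0.67) rose in astrocytes, Neuro-2A and BV-2 on the log2 scale. The mitochondrial ribosome gene Mrps12 rose by 1.20 in Neuro-2A and 0.79 in BV-2, and from 23.7 ± 3.28 to 69.9 ± 2.23 TPM in astrocytes. Other shared rises were the mitotic cyclin Ccnb1 (1.38, 0.73 and 0.97), the ER chaperone Canx (0.96, 0.94 and 0.86), the translocon-associated Serp1 (0.90, 1.04 and 0.81) and the glycosphingolipid enzyme B4galt6 (1.37, 0.77 and 0.61). B4galt6 carried a 7mer-m8 of cel-miR-67, and each of the other 8 carried a cel-miR-67 8mer.

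Of 12626 genes tested in all 3 cell types, 303 were lower in each (25.2 times as many as for independent lists) and 176 were higher in each (23.3 times), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among shared falls with a UTR, 172 of 292 (58.9%) carried a site of the mix, against 19.1% of all genes (odds ratio 6.54, 95% confidence interval 5.12 to 8.38, Fisher's exact test, adjusted p = 1.28e-51). Among shared rises, 98 of 166 (59.0%) carried a cel-miR-67 site, against 11.5% (95% confidence interval of the odds ratio 8.68 to 16.7, Fisher's exact test, adjusted p = 1.88e-49). Both tests treat genes as independent, which they are not, and make no adjustment for UTR length or GC content, so their p-values and intervals are too narrow a guide. Of the shared falls, 33.9% carried miR-199a-3p sites, 33.6% miR-140-5p sites and 5.48% miR-99b-3p sites. Across genes, which are not independent replicates, the fold changes correlated at r = 0.48 for astrocytes and Neuro-2A, 0.33 for astrocytes and BV-2 and 0.34 for Neuro-2A and BV-2 (Spearman 0.47, 0.30 and 0.32). Of genes called in both, 1441 of 1507 (95.6%), 868 of 978 (88.8%) and 528 of 537 (98.3%) changed in the same direction. The shared counts leaned on the BV-2 libraries, with 129, 141 and 146 falls and 93, 93 and 95 rises without BV-2 mix replicates 1, 2 and 3, and 476 falls and 275 rises without BV-2 control replicate 2. Without Neuro-2A mix replicate 3, 106 rises were shared, and with the replicate block in all 3 cell types 271 were. With limma on log2(TPM + 0.1), 180 falls were shared.

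In pairs, astrocytes and Neuro-2A shared 865 falls (253 if the lists were independent) and 576 rises (173). With the replicate block in both cell types they shared 1716 falls and 1665 rises. Their shared falls went to 538 and 467 without Neuro-2A mix replicates 2 and 3 and to 575 and 527 without control replicates 2 and 3. Their shared rises went to 376, 277 and 241 without Neuro-2A mix replicates 1, 2 and 3, to 331 and 300 without control replicates 2 and 3, and to 987 in Neuro-2A numbers 2 and 3 alone. Astrocytes and BV-2 shared 499 falls (162) and 369 rises (142). Without BV-2 mix replicates 1, 2 and 3 these were 186, 198 and 205 falls and 133, 136 and 139 rises. They were 898 falls and 653 rises without BV-2 control replicate 2, 321 falls without control replicate 3, and 252 falls with limma on log2(TPM + 0.1). Neuro-2A and BV-2 shared 330 falls (57.5) and 198 rises (32.8), with 359 rises under the block in both cell types and 205 falls with limma on log2(TPM + 0.1). Without BV-2 mix replicates 1, 2 and 3 they shared 138, 150 and 156 falls and 95, 97 and 99 rises, and without BV-2 control replicate 2 they shared 532 and 326. Without Neuro-2A mix replicate 2 they shared 129 rises, and without mix replicate 3 they shared 219 falls and 117 rises.

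**Figure D1:**
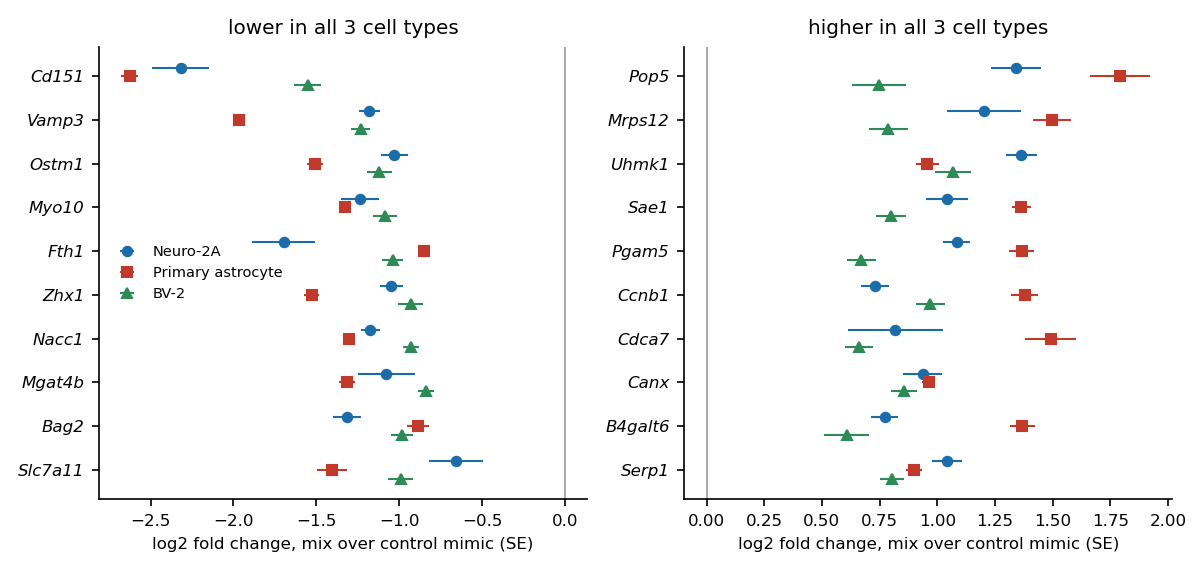
Log2 fold change (mix against control mimic, x axis) of the genes with the largest falls and rises shared by all 3 cell types (y axis), with bars of 1 SE and n = 3 libraries per group. Cd151 lies lowest, at −2.63 in astrocytes, and Pop5 highest, at 1.79 in astrocytes.

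In Neuro-2A cells Cd151, Fth1, Plekhh1 and the neuropilin-like receptor Dcbld2 had the largest falls among the genes named here. Cd151 changed by −2.32 ± 0.171 (SE, n = 3 per group). Dcbld2 fell from 62.6 ± 2.19 to 23.8 ± 1.06 TPM and the macrophage differentiation-associated Mmd, with a miR-140-5p 8mer, from 64.6 ± 1.72 to 25.9 ± 2.3 TPM. Plekhh1 (−1.41), Bag2 (−1.31) and Tmem123 (−1.31) were among the other large falls. The sheddase Adam10 and the γ-secretase subunit Ncstn, which cut Notch and the amyloid precursor in turn and carry miR-140-5p 8mers, changed by −0.83 ± 0.0659 and −0.84 ± 0.0752. The leucine importer Slc7a5 fell from 974 ± 78.1 to 514 ± 54.2 TPM and its partner Slc3a2 from 476 ± 35.8 to 307 ± 24.7 TPM. The silencing factors Ago1 (−0.84), Cnot6 (−0.77) and Cnot7 (−0.61) fell, while the pluripotency RNA-binding gene Lin28a (0.84) rose with a cel-miR-67 8mer. The largest rises after Uhmk1 and Pop5 included Zfp367 (1.05) and the deubiquitinase Usp43 (1.03), neither with a site of the mimics, and the NMDA receptor subunit Grin1 rose by 0.83.

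Of 16160 genes tested in Neuro-2A, 2083 (12.9%) changed, 1273 lower and 810 higher, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the replicate block, 6101 changed (3152 lower and 2949 higher). At least 2 fold, 57 genes were lower and 23 higher, and at 1.5 fold 329 and 143. The 3 mix and 3 control values did not overlap for 5254 genes (32.5%), where chance gives 10%. The values compared are deposited TPM without TMM scaling. The biological coefficient of variation was 8.64%, and 3.17% with the block. Without mix replicates 1, 2 or 3 the count fell to 1370, 1017 and 870, and without control replicates 2 or 3 to 1184 and 1052, while numbers 2 and 3 alone gave 3663 and the fit of all 18 libraries 3271.

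Reported targets of miR-199a-3p and miR-140-5p shifted down as lists in Neuro-2A, as did actin and focal adhesion genes and TGF-β and BMP signalling, by camera with the preset correlation. The laminin-binding integrin Itga3 (−0.88 ± 0.0604), the kinase Pak4 (−0.84 ± 0.0672) and the microtubule-regulating kinase Taok1 (−0.62 ± 0.0563) each carried a miR-199a-3p 8mer. Of 18 tested reported targets of miR-199a-3p, 10 were lower and 1 higher (11 and 1 adjusted over the list alone), with a median of −0.28 (camera adjusted p = 6.41e-10, and adjusted p = 0.063 with an estimated correlation). Of 19 reported targets of miR-140-5p, among them Mmd, Ostm1 and the transcription factor Sox4, 8 were lower and 1 higher (10 and 3 adjusted over the list alone, 12 and 3 with the replicate block), with a median of −0.39 (camera adjusted p = 1.04e-07, and adjusted p = 0.28 with an estimated correlation). Cytoplasmic actin Actg1 fell from 1779 ± 48.3 to 1257 ± 24.4 TPM and the actin crosslinker Flna changed by −0.57. Among 42 actin and focal adhesion genes, 17 were lower and 2 higher (21 and 2 adjusted over the list alone, 22 and 4 with the replicate block), with a median of −0.15 (camera adjusted p = 6.86e-09, and adjusted p = 0.28 with an estimated correlation). In TGF-β and BMP signalling, the signal transducer Smad5 (−0.66) and the receptor Bmpr2 (−0.62) led 9 falls among 29 genes with 0 rises (10 and 2 adjusted over the list alone, 14 and 4 with the block), with a median of −0.13 (camera adjusted p = 0.00265, and adjusted p = 0.343 with an estimated correlation).

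Of 44 cytosolic ribosomal protein genes in Neuro-2A, 0 were lower and 4 higher (0 and 16 adjusted over the list alone, 0 and 38 with the replicate block), with a median of 0.12 (camera adjusted p = 3.36e-06, and adjusted p = 0.671 with an estimated correlation). Rpl18 rose by 0.63, though ribosomal protein genes share reads with many pseudogenes. DNA replication genes, such as the ligase Lig1 (0.30), were lower in 1 and higher in 7 of 37 (1 and 11 adjusted over the list alone, 2 and 20 with the block), with a median of 0.14 (camera adjusted p = 0.00229, 0.079 without control replicate 2, and adjusted p = 0.808 with an estimated correlation). Interferon response genes, mostly weakly expressed here, were lower in 1 and higher in 2 of 31 (1 and 4 adjusted over the list alone, 2 and 12 with the block), with a median of 0.29 (camera adjusted p = 0.0312, and adjusted p = 0.808 with an estimated correlation). That call was lost without mix replicate 2 (0.0801) and without control replicate 1 (0.114). The block added the cholesterol synthesis genes (14 of 24 lower and 1 higher, against 2 and 1; camera adjusted p = 0.0177, against 0.151), the disease-associated microglia genes (4 of 14 lower and 2 higher, 0.0322, against 0.151) and the neuron markers (6 of 9 lower and 0 higher, 0.0145, against 0.0618). With an estimated correlation these 3 blocked values were each 0.58. Without control replicate 1, 11 lists passed instead of 7.

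In primary astrocytes, interferon β, the chemokine Cxcl10, the integrin Itga3 and the water channel Aqp4 were lower in the mix arm than in the control arm, and the cyclin Ccnd1 was higher. Interferon β, Ifnb1 (ENSMUSG00000048806, mm10 chromosome 4, 88522025 to 88522774), fell from 5.47 ± 0.805 to 1.18 ± 0.312 TPM (SD, n = 3). Its mix level includes values at the TPM floor of 1 and is therefore an upper limit. The T cell-attracting chemokine Cxcl10 fell from 2381 ± 140 to 815 ± 82.3 TPM, the antiviral gene Ifit2 from 456 ± 21.7 to 153 ± 15.6 TPM and the immune checkpoint ligand Cd274, with a miR-199a-3p 8mer, from 79.2 ± 4.04 to 20.7 ± 3.7 TPM. Itga3 fell from 110 ± 0.728 to 27.1 ± 1.79 TPM, and the TGF-β-activating integrin Itgb8 changed by −1.36 ± 0.041. The water channel Aqp4 fell from 1796 ± 92.6 to 732 ± 71.3 TPM, and the glutamate transporter Slc1a2 and the bicarbonate transporter Slc4a4 changed by −0.89 ± 0.0549 and −0.88 ± 0.0436. The Wnt antagonist Sfrp1 changed by −1.48 ± 0.0502, while the G1 cyclin Ccnd1 rose from 677 ± 20.9 to 1478 ± 92.8 TPM. Zfp469, which had no annotated UTR, rose by 1.76, and the TGF-β-binding Ltbp1 rose by 1.06. The silencing effector Ago2 rose by 0.76 while Ago1 changed by −0.65.

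Of 17770 genes tested in astrocytes, 7149 (40.2%) changed, 3652 lower and 3497 higher, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median size of a called change was 0.29, against 0.41 in Neuro-2A and 0.36 in BV-2. At least 2 fold, 136 genes were lower and 75 higher, and at 1.5 fold 702 and 442. The groups did not overlap for 9312 genes (52.4%), where chance gives 10%, and the coefficient of variation was 3.52%. That share was read from TPM without TMM scaling, where a shift of all genes between the arms can raise it. The fit of all 18 libraries called 4535. With limma on log2(TPM + 1), which leaves TPM unscaled, the median of all genes moved by 0.06. There 2473 genes were lower and 4946 higher, and the share of rises went from 48.9% to 66.7%. Since that fit changed the test, the measure and the scaling together, the source of the move was not isolated.

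Interferon signalling was the list with the lowest adjusted p in astrocytes, with the antiviral GTPase Mx1 (−1.38) and the dNTPase Samhd1 (−0.95) beside Ifit2 and Cxcl10. Of its 38 genes, 37 were lower and 0 higher, also when adjusted over the list alone, with a median of −0.64 (camera adjusted p = 1.05e-46, and adjusted p = 0.16 with an estimated correlation). The chemokine Ccl7 (−1.34) and the prostaglandin synthase Ptgs2 (−1.09) were among the NF-κB and inflammatory genes, of which 22 of 39 were lower and 3 higher, with the same counts adjusted over the list alone (median −0.27, camera adjusted p = 0.00072, and adjusted p = 0.675 with an estimated correlation). Astrocyte reactivity genes, such as the hyaluronan receptor Cd44 (−0.82) and the GTPases Iigp1 (−1.18) and Gbp2 (−0.98), were lower in 18 and higher in 3 of 36 (20 and 3 adjusted over the list alone, median −0.18, camera adjusted p = 6.13e-06, and adjusted p = 0.396 with an estimated correlation). Reported miR-199a-3p targets were lower in 19 and higher in 1 of 23, also over the list alone, with a median of −0.49 (camera adjusted p = 8.75e-22). This was the only list of the 3 cell types past 0.05 with an estimated correlation (adjusted p = 0.0179). Reported miR-140-5p targets, including the oxidative stress regulator Nfe2l2 (−0.83), were lower in 12 and higher in 3 of 24 (13 and 3 adjusted over the list alone, median −0.17, camera adjusted p = 6.13e-06, and adjusted p = 0.109 with an estimated correlation).

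Cholesterol synthesis and uptake genes fell in astrocytes, among them the sterol desaturase Sc5d (−1.01) and the HMG-CoA synthase Hmgcs1 (−0.58). Of 25, 18 were lower and 1 higher (20 and 1 adjusted over the list alone, median −0.39, camera adjusted p = 8.84e-13, and adjusted p = 0.16 with an estimated correlation). Glutamate and potassium handling genes, with Aqp4, Slc4a4 and Slc1a2, were lower in 11 and higher in 2 of 15, also over the list alone (median −0.31, camera adjusted p = 2.58e-07, and adjusted p = 0.332 with an estimated correlation). Astrocyte markers were lower in 6 of 10 and higher in 0 (9 and 0 adjusted over the list alone, median −0.26, camera adjusted p = 6.13e-06, and adjusted p = 0.241 with an estimated correlation). Among 44 actin and focal adhesion genes, 27 were lower and 2 higher (28 and 3 adjusted over the list alone, median −0.15, camera adjusted p = 4.69e-09, and adjusted p = 0.232 with an estimated correlation). ER stress and amino acid response genes, with Slc7a11 and Slc7a5 (−0.78), were lower in 13 and higher in 4 of 32 (14 and 4 adjusted over the list alone, median −0.13). Their camera adjusted p was 0.0274, 0.098 with limma on log2(TPM + 0.1), and adjusted p = 0.241 with an estimated correlation.

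Proliferation genes rose in astrocytes, with the mitotic genes Anln (0.76) and Bub1b (0.53) beside Ccnb1. Of 34 mitosis genes, 30 were higher and 0 lower (31 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 1.10e-11, and adjusted p = 0.515 with an estimated correlation). Replication helicase genes Mcm5 (0.66) and Mcm2 (0.69) and the ribonucleotide reductase gene Rrm2 (0.56) were among 28 of 37 DNA replication genes that were higher, with 0 lower, also over the list alone (median 0.33, camera adjusted p = 9.99e-09, and adjusted p = 0.398 with an estimated correlation). Ribosomal protein genes were higher in 31 and lower in 0 of 44 (32 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 2.15e-05, and adjusted p = 0.834 with an estimated correlation). Oxidative phosphorylation genes, such as the complex I subunit Ndufa6 (0.65, cel-miR-67 8mer), were higher in 12 and lower in 1 of 38 (9 and 1 adjusted over the list alone, median 0.07). Their camera adjusted p was 0.0356, with 0.0824 without mix replicate 3, 0.119 without control replicate 2, and adjusted p = 0.911 with an estimated correlation.

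In BV-2 cells fewer genes changed at least 2 fold than in the other cell types, with the cytokine Il1f9 and Cd151 among the largest falls. The IL-36 cytokine Il1f9 fell from 5.68 ± 0.469 to 1.99 ± 0.359 TPM (SD, n = 3). The glutathione synthesis gene Gclm fell from 41.5 ± 5.14 to 20.7 ± 1.74 TPM, the cystine importer Slc7a11, with a miR-140-5p 8mer, changed by −0.99 ± 0.0747, and the stress regulator Nfe2l2 changed by −0.64 ± 0.0458. The lipoprotein lipase Lpl fell from 614 ± 35.7 to 399 ± 7.27 TPM, and the scavenger receptor Cd36 and the complement receptor C3ar1 changed by −0.71 ± 0.0627 and −0.53 ± 0.0491. The LPS co-receptor Cd14 fell from 637 ± 59.3 to 470 ± 8.21 TPM. The receptor Treml4 (−1.20) and Tmem39b (−1.17) also fell, without sites of the mix. The lectin-like receptor Klra17 (1.35) and the MYC antagonist Mxd3 (1.14) rose from low levels of 2.07 ± 0.226 and 3.77 ± 0.122 TPM.

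Of 14961 genes tested in BV-2, 1498 (10.0%) changed, 809 lower and 689 higher, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2 fold, 26 genes were lower and 28 higher, and at 1.5 fold 141 and 142. The groups did not overlap for 4903 genes (32.8%), where chance gives 10%, and the coefficient of variation was 6.92%. That share too was read from TPM without TMM scaling, where a shift of all genes can raise it. With limma on log2(TPM + 1), 430 genes were lower and 925 higher, and the share of rises went from 46.0% to 68.3%. The median of all genes moved by 0.07. The test, the measure and the scaling changed together here, so the source of the move was not isolated. The count was 434, 458 and 481 without mix replicates 1, 2 and 3, 2985 without control replicate 2, which stood apart from its group, and 913 without control replicate 3.

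In BV-2, reported targets, ER stress and amino acid response genes and actin genes shifted down as lists and mitosis genes up, by camera with the preset correlation. Cd44 (−0.68 ± 0.048) and Adam10 (−0.40 ± 0.0596) were among the 12 lower of 21 reported miR-199a-3p targets, with 0 higher (13 and 1 adjusted over the list alone, median −0.28, camera adjusted p = 6.0e-08, and adjusted p = 0.39 with an estimated correlation). Of 17 reported miR-140-5p targets, 6 were lower and 2 higher (6 and 3 adjusted over the list alone, median −0.16). Their camera adjusted p was 0.00306, with 0.0762 by limma on log2(TPM + 0.1) and adjusted p = 0.577 with an estimated correlation. The stress transcription factor Atf3 (−0.51), asparagine synthetase Asns (−0.44) and Slc7a5 (−0.45) were among 10 of 31 ER stress and amino acid response genes that were lower, with 0 higher (13 and 1 adjusted over the list alone, median −0.14, camera adjusted p = 1.23e-07, and adjusted p = 0.436 with an estimated correlation). Tropomyosin Tpm4 (−0.37) and the Arp2/3 subunit Arpc2 (−0.34) were among 13 of 40 actin and focal adhesion genes that were lower, with 0 higher (18 and 0 adjusted over the list alone, median −0.16, camera adjusted p = 4.89e-06, and adjusted p = 0.39 with an estimated correlation). Mitosis genes, with Ccnb1 and Anln (0.43), were higher in 10 and lower in 0 of 34 (17 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 1.93e-08, and adjusted p = 0.81 with an estimated correlation).

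Disease-associated microglia genes, among them Lpl and Fth1, were lower in 6 and higher in 2 of 25 in BV-2 (10 and 3 adjusted over the list alone, median −0.09). Their camera adjusted p was 0.00108, with 0.0762 by limma on log2(TPM + 0.1) and adjusted p = 0.633 with an estimated correlation. Neuronal and synapse genes were higher in 4 and lower in 0 of 11 (5 and 0 adjusted over the list alone, median 0.19). Their camera adjusted p was 0.0079, with 0.112 by limma on log2(TPM + 0.1) and adjusted p = 0.577 with an estimated correlation. Without control replicate 3, 11 lists passed in BV-2 instead of 7.

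The other pathway lists passed in none of the 3 cell types. These were mTOR signalling, autophagy, lysosome, p53 targets, apoptosis, glycolysis and hypoxia, extracellular matrix, YAP and TAZ targets, Notch, Wnt, microRNA machinery, homeostatic microglia and phagocytosis receptors, with medians from −0.13 to 0.09 and camera adjusted p from 0.123 to 0.989. The neuron, microglia and macrophage, oligodendrocyte lineage, endothelial, fibroblast and pericyte, and ependymal markers had medians from −0.32 to 0.15 where at least 5 were tested, with camera adjusted p from 0.0618 to 0.989. Single members still moved, such as the lysosomal lipase Lipa, which rose by 0.90 in astrocytes and changed by −0.35 in BV-2, and the laminin Lamc1, which changed by −0.88 in Neuro-2A and −0.70 in astrocytes. Of the 4 host genes of the microRNAs, 4, 3 and 2 were tested in Neuro-2A, astrocytes and BV-2, too few for a test of the list. Their medians were −0.21, −0.20 and −0.15 in that order. In every list past the threshold, the median, mean and test had the same sign. Among the lists that did not pass, they differed in sign for autophagy, mitosis, ER stress, glycolysis, neuronal genes and astrocyte reactivity in Neuro-2A, for apoptosis, Notch, microRNA machinery, disease-associated microglia and phagocytosis in astrocytes, and for extracellular matrix, NF-κB and astrocyte reactivity in BV-2.

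**Figure D2:**
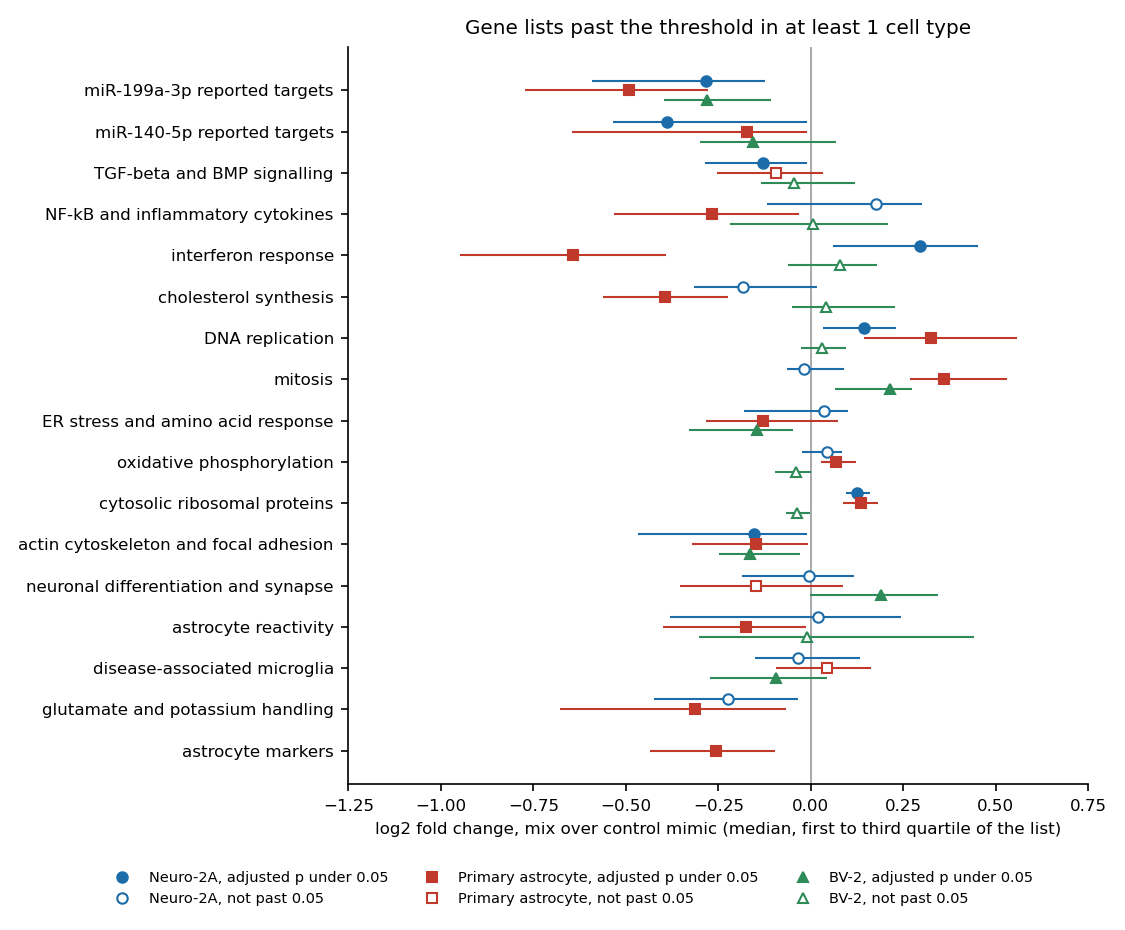
Median log2 fold change (mix against control mimic, x axis) of the gene lists past the threshold in at least 1 cell type (y axis), with bars from the lower to the upper quartile of the list's genes. Filled points passed camera with the preset correlation, and the interferon response lies lowest in astrocytes, at −0.64.

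Genes with 8mer sites of miR-199a-3p and miR-140-5p had negative median fold changes in all 3 cell types. Genes with a miR-199a-3p 8mer had a median of −0.21 in Neuro-2A (331 genes), −0.27 in astrocytes (379 genes) and −0.12 in BV-2 (308 genes), and 36.3%, 56.7% and 23.4% of them were called lower. The medians for miR-140-5p 8mers were −0.21, −0.15 and −0.09, and those for miR-99b-3p 8mers, in only 26, 30 and 18 genes, were −0.24, −0.16 and −0.02. Genes with a cel-miR-67 8mer had medians of 0.09, 0.15 and 0.05, higher in the mix arm. Cd151, Itga3, Vamp3 and Slc7a5 carried miR-199a-3p 8mers, and Mmd, Adam10, Ncstn and Ostm1 carried miR-140-5p 8mers.

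In Neuro-2A, camera among 12584 genes with a UTR placed the 1044 miR-199a-3p site genes (median −0.15, adjusted p = 1.73e-12), the 266 miR-99b-3p site genes (−0.10, 3.45e-05) and the 1359 miR-140-5p site genes (−0.12, 5.29e-09) below the others, and the 1398 cel-miR-67 site genes above them (0.06, 0.00013). With an estimated correlation the adjusted p-values were 0.000978, 0.00886, 0.00522 and 0.00886. In astrocytes (14225 genes) camera gave medians of −0.15, −0.09, −0.09 and 0.11 for the 4 microRNAs in this order (adjusted p = 4.78e-12, 0.0002, 4.97e-05 and 4.02e-06). With an estimated correlation these were 0.00535, 0.0503, 0.0503 and 0.0178. In BV-2 (11454 genes) camera gave medians of −0.06, −0.01, −0.04 and 0.06 (adjusted p = 0.000263, 0.0863, 0.00913 and 4.49e-05), and 0.386, 0.419, 0.386 and 0.321 with an estimated correlation, so no set held there. In BV-2, miR-99b-3p site genes passed without control replicate 2 (0.00755), and miR-140-5p site genes did not pass without control replicate 3 (0.0558).

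Among genes called lower, 46.9% in Neuro-2A, 34.0% in astrocytes and 38.9% in BV-2 carried a site of any of the 3 microRNAs, against 18.7%, 19.4% and 18.9% of all tested genes with a UTR (Fisher's exact test, odds ratios 4.72, 2.96 and 3.01). Of the genes called higher, 29.7%, 19.6% and 29.5% carried a cel-miR-67 site, against 11.1% of genes in each cell type (odds ratios 3.83, 2.57 and 3.75). Fisher's test treats genes as independent here too, without adjustment for UTR length or GC content. Per library, miR-199a-3p site genes of the mix arm lay at −0.18 ± 0.0137, −0.20 ± 0.00757 and −0.08 ± 0.00652 against genes without a site, relative to the control mean, in Neuro-2A, astrocytes and BV-2 (SD, n = 3). The cel-miR-67 site genes lay at 0.10 ± 0.00867, 0.14 ± 0.00743 and 0.08 ± 0.00256. Exact permutation tests of these values gave p = 0.1, the smallest that 3 against 3 allows, for each set except miR-140-5p (0.2) and miR-99b-3p (0.3) in BV-2. There the control libraries ranged from −0.06 in replicate 2 to 0.04 in replicate 3 for miR-199a-3p sites.

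**Figure D3:**
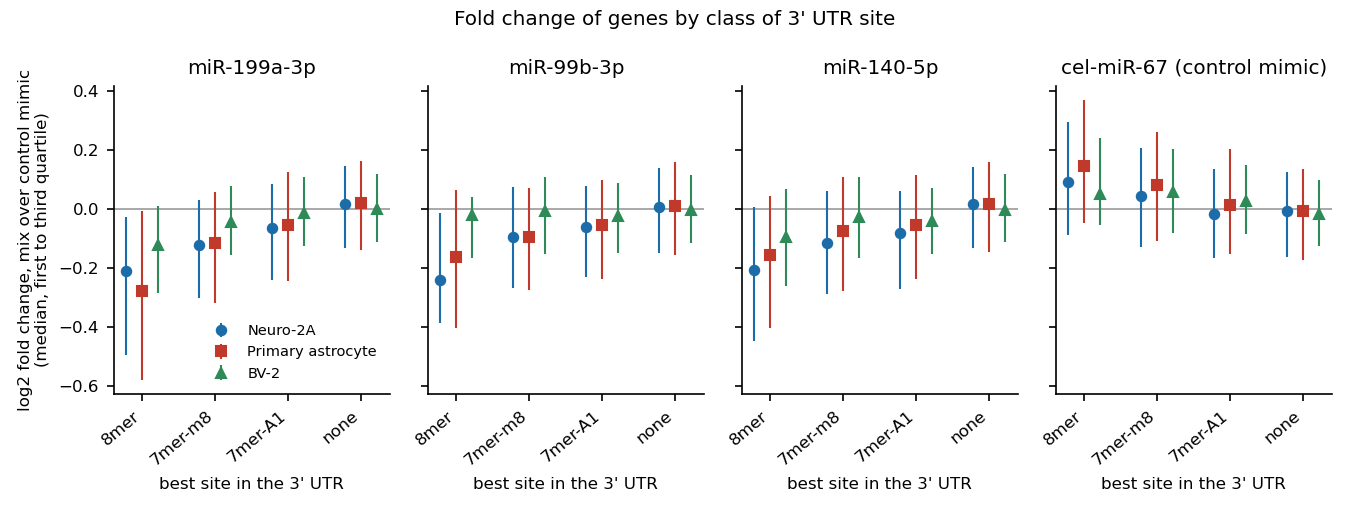
Median log2 fold change (mix against control mimic, y axis) of genes by site class of each microRNA (x axis) in the 3 cell types, with bars from the lower to the upper quartile of the genes. The miR-199a-3p 8mer median lies at −0.27 and the cel-miR-67 8mer median at 0.15 in astrocytes.

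**Figure D4:**
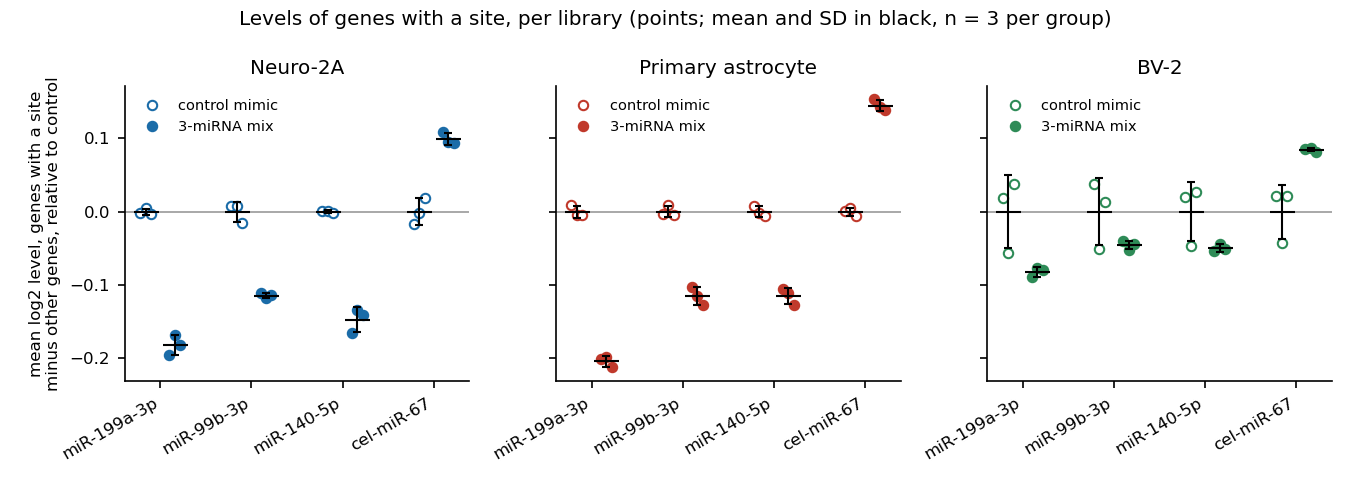
Mean log2 level of site genes against genes without a site, relative to the control mean (y axis), for each library of both arms (points) with the group mean and SD as a bar. The BV-2 control libraries spread from −0.06 to 0.04 for miR-199a-3p sites.

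Single genes such as Itga3, Qk and Slc4a8 responded differently in at least 1 pair of cell types. The data hold no measure of how much mimic entered each cell type, so these differences may include it. Itga3 changed by −2.08 in astrocytes and −0.88 in Neuro-2A, a difference of −1.20 ± 0.0903 (SE), and the RNA-binding gene Qk changed by −0.92 in astrocytes and 0.04 in Neuro-2A, a difference of −0.95. The septin Sept2 rose by 0.81 in astrocytes and 0.11 in Neuro-2A, a difference of 0.71. The chromatin gene Hmga1 rose by 1.16 in astrocytes and changed by −0.02 in BV-2, a difference of 1.19, but it shares reads with its copy Hmga1b (difference 1.23) and is uncertain. The GPI anchor gene Pigq changed by −1.18 in astrocytes and −0.33 in BV-2, a difference of −0.83. The bicarbonate transporter Slc4a8 changed by −0.14 in Neuro-2A and rose by 1.01 in BV-2, a difference of −1.14, and Mmd (−1.30 and −0.06) and Dcbld2 (−1.38 and −0.51) fell more in Neuro-2A. With the replicate block, Sept2 (adjusted p = 0.0224) and Slc4a8 (adjusted p = 0.00783) also passed within Neuro-2A by edgeR's quasi-likelihood test.

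Among 20308 genes in the fit of all 18 libraries, 951 had a different effect in astrocytes and Neuro-2A (573 more positive in astrocytes and 378 more negative), 1432 in astrocytes and BV-2 (721 and 711) and 713 in Neuro-2A and BV-2 (295 and 418 relative to Neuro-2A), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 20308 genes, 14489, 13651 and 13149 were tested within both cell types of these pairs, so the counts can include genes not tested within both. With the replicate block the counts were 1982, 2644 and 1630, and with limma on log2(TPM + 0.1) they were 3010, 2963 and 1856. The named differences had adjusted p-values from 2.89e-07 for Hmga1 to 1.39e-05 for Sept2. Without astrocyte mix replicate 1, control replicate 2 or control replicate 3, the difference between astrocytes and Neuro-2A held 582, 547 and 619 genes, and that between astrocytes and BV-2 held 905 without astrocyte control replicate 2. The difference between Neuro-2A and BV-2 held 467 and 457 without Neuro-2A mix replicates 2 and 3, and 358, 372 and 348 without BV-2 mix replicates 1, 2 and 3.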

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

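Of the tests in this part, the interaction tests of genes, the rank of the cel-miR-67 heptamer and the other splits of the libraries were chosen before their results were seen, and the remaining tests after. Groups of 3 libraries are too small for a test of single libraries that stand apart, so every result listed here is a difference between cell types or a pattern weighed for its source.

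Genes with a cel-miR-67 site were higher in the mix arm of all 3 cell types by camera with the preset correlation, a call lost in BV-2 with an estimated correlation (adjusted p = 0.321). Among all heptamers of 3′ UTRs, the heptamer that pairs with the seed of cel-miR-67, GGTTGTG, ranked 1 for a higher fold change in each cell type, which is consistent with seed activity of the control mimic in the control arm. UTR length and GC content did not account for it, since the highest adjusted p over the 3 cell types was 0.000447 after adjustment for them, with the preset correlation. The rises of Pop5, Uhmk1 and Canx may then be release from the control mimic and not an effect of the mix, a hypothesis found and tested on the same data.

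Interferon response genes were lower in the mix arm of astrocytes by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.16). Of the 37 that fell, 9 (24.3%, 95% confidence interval 13.4% to 40.1%) carried a site of the mix, against 19.4% of all tested genes, so direct sites in most of these genes are unlikely. The microglia and macrophage markers had a median of 0.0513, against −0.64 for the interferon list, which speaks against fewer microglia in the mix cultures. Ifnb1 stood at 5.47 TPM in the control arm, and without untransfected cells the data cannot tell a response raised by the control mimic from a response lowered by the mix.

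Replicate 1 of Neuro-2A stood apart from replicates 2 and 3 in both arms. The deviations of the 2 libraries numbered 1 correlated at 0.587, which is consistent with a batch shared by libraries of that number. Lower depth did not account for it, since control replicate 1 held 22.3 M counts, the most of its group. Values with the replicate number as a block are given in the report where they changed a call.

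The effect of the mix differed between astrocytes and Neuro-2A for 951 genes, between astrocytes and BV-2 for 1432 and between Neuro-2A and BV-2 for 713, each by edgeR's interaction test. Among 50 drawn splits within the cell types, only the real split, 1 of 50, gave as many in each pair, and the highest others gave 2, 1 and 1. A split that mixes the arms puts the mix effect into the spread between libraries, which lowers its counts, so this draw says little about chance. Astrocytes minus Neuro-2A gave −1.20 for Itga3, −0.95 for Qk and 0.71 for Sept2. Astrocytes minus BV-2 gave 1.19 for Hmga1, 1.23 for Hmga1b and −0.83 for Pigq. Neuro-2A minus BV-2 gave −1.14 for Slc4a8, −1.23 for Mmd and −0.86 for Dcbld2.

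Differences of whole lists and site sets were tested by camera on the interaction statistics, and 27 passed with the preset correlation. With an estimated correlation the lowest adjusted p of these was 0.0712, so 0 passed. The lists could include members not tested within both cell types, such as 38 interferon response genes against 31 tested within Neuro-2A. Against Neuro-2A, the effect in astrocytes was more negative for NF-κB genes (adjusted p = 2.79e-05), interferon response (1.03e-31) and cholesterol synthesis (3.56e-06), and more positive for DNA replication (6.74e-07) and mitosis (9.98e-26). Against BV-2, camera placed the astrocyte effect lower for reported miR-199a-3p targets (0.00239), NF-κB genes (2.07e-05), interferon response (1.21e-38), cholesterol synthesis (1.65e-14), astrocyte reactivity (0.0346), miR-199a-3p sites (0.00019) and miR-140-5p sites (0.0469). It was higher for DNA replication (7.64e-15), mitosis (7.99e-08), oxidative phosphorylation (5.35e-06) and ribosomal proteins (2.38e-12). Against BV-2, the Neuro-2A effect was lower for cholesterol synthesis (8.04e-05), mitosis (1.45e-07), Notch signalling (0.0454), microRNA machinery (0.000598) and the sites of miR-199a-3p (0.00016), miR-99b-3p (0.0148) and miR-140-5p (0.00113). It was higher for DNA replication (0.000598), ER stress (0.0138), oxidative phosphorylation (0.000945) and ribosomal proteins (6.49e-15).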

How the results depend on the processing

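Leaving out number 1 of both Neuro-2A arms and the filter of TPM above 1 were added after the data had been seen. So was limma on log2(TPM + 1) as an alternative to the counts. Depth of 18.5 to 27.9 M counts limits genes with low counts, and 3 libraries per arm limit every test. DESeq2 called 2240, 5352 and 1527 genes in Neuro-2A, astrocytes and BV-2. In every alternative 0 of the called genes passed in the opposite direction.

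In Neuro-2A, 3271 genes changed in the fit of all 18 libraries, 6101 with the replicate block and 3663 in numbers 2 and 3 alone, where 11 lists passed. With an estimated correlation 0 lists passed in Neuro-2A, 1 in astrocytes and 0 in BV-2. The site sets then had adjusted p = 0.0503 for miR-99b-3p and 0.0503 for miR-140-5p in astrocytes, and 0.386 for miR-199a-3p, 0.386 for miR-140-5p and 0.321 for cel-miR-67 in BV-2. The fit of all 18 libraries gave 4535 genes in astrocytes. With 8mer sites only, miR-99b-3p sites in BV-2 passed (0.0212). With limma on log2(TPM + 0.1), 4 lists passed in BV-2, 180 genes were lower in all 3 cell types, and the effects differed for 3010 genes in astrocytes minus Neuro-2A, 2963 in astrocytes minus BV-2 and 1856 in Neuro-2A minus BV-2. The block gave 1982, 2644 and 1630 for these differences and 271 shared rises. The cause was not tested.

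Leaving out a library in turn gave 870 to 2268 genes and 6 to 11 lists in Neuro-2A, 5767 to 6775 genes and 13 to 15 lists in astrocytes, and 434 to 2985 genes and 7 to 11 lists in BV-2. In BV-2, the adjusted p ranged from 0.00755 to 0.323 for miR-99b-3p sites and from 0.000292 to 0.0558 for miR-140-5p sites. The differences ranged from 547 to 1329, 905 to 1808 and 348 to 1060 genes, the shared falls from 129 to 476 and the shared rises from 93 to 275. The cause was not tested.

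Genes near 0 changed sign without passing the threshold. Qk in Neuro-2A ranged from −0.00727 without mix replicate 2 to 0.0682 without mix replicate 1. In BV-2, Hmga1 rose to 0.0525 and 0.0525, Hmga1b to 0.0627 and 0.0628 and Mmd to 0.00328 and 0.00355 with limma on log2(TPM + 1) and log2(TPM + 0.1), and Hmga1b to 0.00334 with TPM of at least 5. Leaving out a library moved Hmga1 from −0.0395 to 0.0216 and Hmga1b from −0.0461 to 0.0408. The cause was not tested.

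Apart from the blocked values given in the report and those of the Nfe2l2 targets, the block changed no other call of a reported result in Neuro-2A. In astrocytes every library correlated best with its own number and the block gave 8218 genes, and in BV-2 number 3 did not and the block gave 1493.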

Other observations

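The Nfe2l2 target list was chosen after the values of Fth1, Slc7a11 and Gclm had been seen, while the other tests of this part were fixed before their results, except the comparison of Neuro-2A replicate 1 with the others.

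Several antioxidant genes fell together. Nfe2l2, which switches on genes against oxidative stress, changed by −0.83 in astrocytes, −0.64 in BV-2 and −0.39 in Neuro-2A (adjusted p = 0.222 by edgeR), and its UTR held only a 7mer-A1 of miR-140-5p. The sulfiredoxin gene Srxn1 changed by −0.77 in astrocytes and −1.05 in BV-2, while the glutathione reductase gene Gsr rose by 0.76 and 0.25. In Neuro-2A neither passed by edgeR, with −0.78 for Srxn1 (adjusted p = 0.143) and 0.29 for Gsr (adjusted p = 0.194). If lower Nfe2l2 output were the source, its other targets should be lower in all 3 cell types. By camera with the preset correlation they were in 2 without the replicate block, and in Neuro-2A only with it. Of 17, 10 were lower and 2 higher in astrocytes (median −0.14, camera adjusted p = 0.0106, and adjusted p = 0.275 with an estimated correlation). In BV-2, 8 of 17 were lower and 1 higher (−0.18, camera adjusted p = 6.7e-10, and adjusted p = 0.0988 with an estimated correlation). In Neuro-2A, 1 of 16 was lower (−0.20, camera adjusted p = 0.112, and adjusted p = 0.617 with an estimated correlation), and 9 were lower and 2 higher with the replicate block (camera p = 0.0018, and p = 0.223 with an estimated correlation). The block also brought Nfe2l2 (adjusted p = 2.04e-05), Srxn1 (5.67e-08) and Gsr (0.000156) past the threshold in Neuro-2A by edgeR. Since the Neuro-2A call rested on the block and no cell type passed with an estimated correlation, the data cannot tell whether lower output of Nfe2l2 is the source.

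Genes with sites of 2 or 3 microRNAs of the mix had lower medians than genes with sites of 1, at −0.20 against −0.11 in Neuro-2A (290 and 1946 genes), −0.19 against −0.08 in astrocytes (333 and 2297) and −0.06 against −0.04 in BV-2 (262 and 1815). The permutation test gave adjusted p = 1.5e-05, 1.5e-05 and 0.125, with genes treated as independent, which they are not. It also made no adjustment for UTR length or GC content, which may differ between these groups. Whether sites of more than 1 microRNA add up therefore stayed open.

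For a lower fold change, the miR-199a-3p heptamer ACTACTG ranked 1 of all heptamers in each cell type, that of miR-140-5p ranked 2, 3 and 4 in Neuro-2A, astrocytes and BV-2, and that of miR-99b-3p ranked 35, 22 and 76. The heptamers of the 3 opposite strands ranked from 8093 to 15934 over the 3 cell types, of at least 16060 heptamers, which speaks against activity of all 3 opposite strands.

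Between number 1 and numbers 2 and 3 of Neuro-2A, 4253 of 16160 genes differed by edgeR's quasi-likelihood test, 2285 lower and 1968 higher in number 1. Lysosome (25 of 37 lower), glycolysis and hypoxia (24 of 30 lower) and ER stress genes (20 of 31 lower) were lower there and cholesterol synthesis genes (19 of 24) higher, with camera adjusted p from 2.72e-19 to 2.66e-10, and from 0.296 to 0.38 with an estimated correlation.

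The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For genes, the real split gave 2083, 7149 and 1498 in Neuro-2A, astrocytes and BV-2, and the highest other split 0 in each, so 1 split reached the real value. For lists, the real splits gave 7, 14 and 7 and the highest others 17, 16 and 13, with 7, 4 and 8 splits giving as many. For site sets, the real splits gave 4, 4 and 3 and the highest others 4, 4 and 3, with 4, 5 and 4 splits giving as many. Every other split set unequal numbers of mix libraries against each other, so part of the mix effect stayed in its comparison. Lists and site sets that passed in those splits may hold that remaining effect. Their counts therefore do not show what chance gives, and no conclusion is drawn from them. In Neuro-2A, the splits with 17 and 16 lists put mix replicate 1 and control replicate 1 together, a structure of the samples. The other splits that parted all 3 numbered pairs gave 6, 6 and 4 lists and 4, 4 and 3 site sets. For the shared genes, 1 of 100 drawn combinations, the real splits, gave as many, with 303 falls and 176 rises against highest others of 0 and 0. Because every other split called 0 genes, no other combination could share any, so this draw adds nothing to the 10 splits.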
